A study of Homo sapiens with 6 samples.

How the data were processed

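Total RNA was extracted from HUVEC and turned into biotinylated cRNA for Affymetrix arrays, per the labels' protocols. HUVEC are endothelial cells of the umbilical vein. The deposited table holds, for each of 54675 probe sets and 6 arrays, a signal intensity on a linear scale, and MAS5 is named for it in the submitters' processing notes. The version and settings of MAS5, and any detection calls, are not given in the sources used here. The values themselves show a scaling of each array by a single factor: the mean after leaving out 2% of probe sets at each end was 150 on all 6 arrays. No further normalization between arrays was seen, and the values are relative brightness in arbitrary units. MAS5 subtracts mismatch signal, so that dim probe sets are noisy, and signals near or below the pseudocount have little meaning. Scaling to a common mean assumes a like total signal per array, and the median signal of ERG siRNA replicate 2 (22.8) lay above those of the other arrays (17.2 to 19.1).

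Groups were taken from the sample labels: ERG siRNA, non-sense siRNA and control vector, with 2 arrays each that the submitters label as biological replicates. Whether the replicates came from separate donors is not stated. The design text speaks of transfection and the sample labels of infection for the vector group, so how the vector was delivered, and what vector it was, is open. The dose of siRNA and the time after it are not given in the sources used here.

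Genes were assigned through a table of the array platform's annotation: 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none, and 41043 of the first kind matched a gene of RefSeq's human annotation by gene identifier. Probe sets with several symbols or none were tested but never named. The 62 control probe sets and 95 probe sets of sex-linked genes were left out of all tests.

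Values were analysed as log2(signal + 16), on which fold changes of dim genes are understated. The upper 60% of probe sets by mean log2 value over all arrays were tested, which left 32711 probe sets. For gene counts 1 probe set per gene was chosen, the brightest by mean log2 value with a single symbol, leaving out sets whose identifier ends in _x_at where the gene had another, which gave 13930 genes. Linear models were fitted with limma (version 3.58.1, R version 4.3.3) to all 6 arrays with a mean per group and no covariate, which leaves 3 residual degrees of freedom, and moderated with eBayes (2.34 prior degrees of freedom). Tests were two-sided, and p-values were adjusted after Benjamini and Hochberg over the probe sets tested in each comparison, with a threshold of 0.05. With 2 arrays against 2, an exact permutation test cannot give a two-sided p below 0.333, so no such test was used. Figures were drawn with matplotlib (version 3.10.9).

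The design, the 26 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. For ERG siRNA against non-sense siRNA the named genes are the 10 largest rises and 10 largest falls among genes past the threshold there, with the same sign against vector, whose ERG siRNA arrays both lie outside the range of the 4 control arrays. For non-sense siRNA against vector they are the 5 largest rises and 5 largest falls past the threshold whose non-sense siRNA arrays both lie outside the range of the 2 vector arrays. In each list up to 4 members with the smallest p are named. Any further gene named completes a count of 5 or fewer or illustrates a pattern and was chosen after its values were seen. List shifts were tested with camera in limma on the chosen probe sets, with a preset inter-gene correlation of 0.01, and adjusted over the 26 lists within each comparison. With the correlation estimated from the residuals 0 of 26 lists passed in any of the 3 comparisons, with 3, 3 and 1 at an unadjusted p under 0.05, in the order ERG siRNA against non-sense siRNA, ERG siRNA against vector, and non-sense siRNA against vector. Of the 26 lists 1 is not reported here. Lists share members, such as TAGLN, CXCL8, HMOX1 and CLDN5.

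The fit was tested on simulated data with 200 changed probe sets among 32711. For ERG siRNA against non-sense siRNA it recovered 1.49% of sets changed by 1.5 times, 17.9% of those changed 2-fold and 83.3% of those changed 4-fold. For ERG siRNA against vector the shares were 1.49%, 10.4% and 80.3%, and for non-sense siRNA against vector 1.49%, 10.4% and 84.8%. The recovered sets all had the right sign. Small changes were therefore mostly missed in this simulation with 2 arrays per group. The number of changed sets moves the adjusted threshold, and 3162 sets passed for ERG siRNA against non-sense siRNA in the data. These shares therefore need not hold for the data. In a simulated comparison of ERG siRNA with non-sense siRNA, camera found the 1 list shifted by 0.5 on the log2 scale. It called 0 of the unshifted lists. The simulated genes varied independently of each other, so this check cannot bear on the preset inter-gene correlation.

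Alternatives were a pseudocount of 1 or 64, no filter or the upper 40% of probe sets, quantile normalization or centring of arrays on the median, the replicate number as a block, only the arrays compared, an intensity-dependent prior (limma-trend), a 2-fold minimum, an adjusted p under 0.1, an estimated inter-gene correlation, the mean of all probe sets of a gene, and leaving out each array in turn.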

Results

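Gene expression was measured in human umbilical vein endothelial cells (HUVEC), cultured cells from the lining of the umbilical vein, on Affymetrix arrays of 54675 probe sets. ERG is a transcription factor of the ETS family that is abundant in endothelial cells. The 6 arrays fall into 3 groups of 2 biological replicates: cells given a small interfering RNA (siRNA) against ERG, cells given a non-sense siRNA, and cells given a control vector. Each array was scaled to a trimmed mean signal of 150, and the median signal lay between 17.2 and 22.8. Replicates correlated at 0.977 (ERG siRNA), 0.984 (non-sense siRNA) and 0.985 (control vector) across the 32711 probe sets tested, and probe sets are not independent replicates. The 3' to 5' signal ratios lay between 0.970 and 1.054 for ACTB and between 0.945 and 1.069 for GAPDH. Precision is limited by the number of arrays, 2 per group.

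ERG itself was lower in both arrays of cells given its siRNA. The brightest of 4 ERG probe sets read 262.0 and 287.8 in these arrays, 1803.4 and 1503.5 with non-sense siRNA, and 1654.8 and 1709.1 with control vector. The mean of 274.9 ± 18.2 (SD, n = 2) was 16.6% of the mean with non-sense siRNA (1653.5 ± 212.1) and 16.3% of the mean with vector (1681.9 ± 38.4). On the log2 scale ERG fell by 2.52 against non-sense siRNA (SE 0.14, limma adjusted p = 0.0049) and by 2.55 against vector (SE 0.14, adjusted p = 0.0082). The 3 other ERG probe sets stood at 27.3%, 42.1% and 23.2% of the non-sense level and all passed there, while the first of them missed the threshold against vector (log2 fold change -1.54, adjusted p = 0.051). With 1 array left out the log2 fold change stayed between -2.65 and -2.39 against non-sense siRNA, and the call was lost without non-sense siRNA replicate 1 (adjusted p = 0.060) or 2 (0.063). Against vector it stayed between -2.61 and -2.48. The call there was lost without any single array, with adjusted p of 0.072 and 0.051 (ERG siRNA replicates 1 and 2), 0.051 and 0.051 (non-sense siRNA) and 0.129 and 0.124 (control vector). It was also lost in a fit to the arrays of these 2 groups only (-2.55, adjusted p = 0.051).

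**Figure D1:**
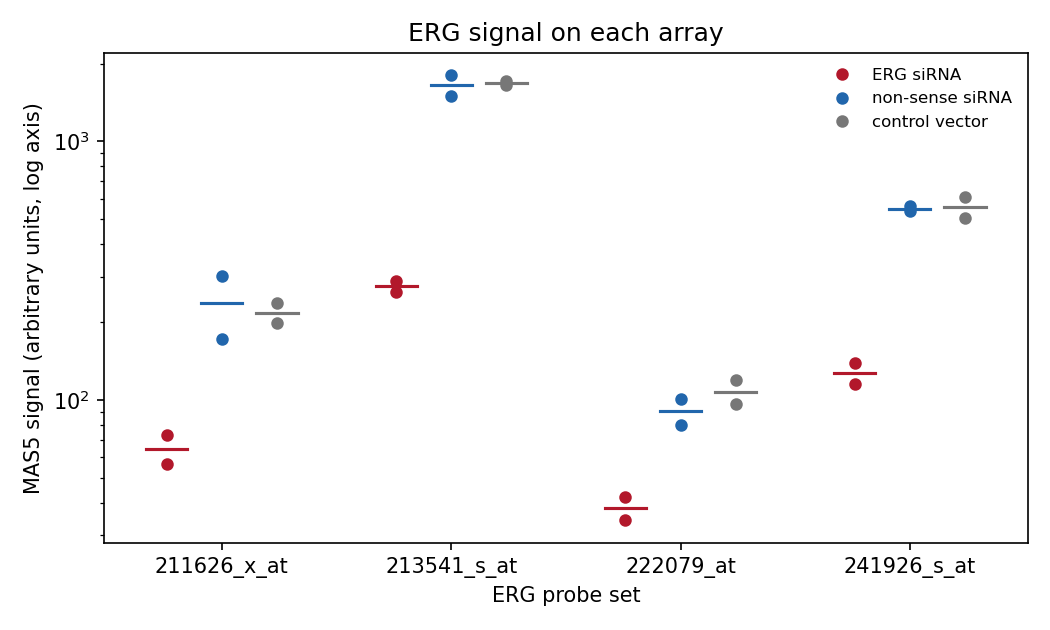
Signal of the 4 ERG probe sets (x axis) in arbitrary units on a log axis, with a point per array and a line at the mean of each group of 2 arrays. Both ERG siRNA arrays lie below all 4 control arrays at each probe set, with a mean of 274.9 against 1653.5 and 1681.9 at the brightest of them.

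The comparison of ERG siRNA with non-sense siRNA asks which genes follow ERG in cells that received an siRNA in both arms. Among the largest rises were those of TAGLN and MYL9. TAGLN, encoding the actin-binding protein transgelin of smooth muscle, had a mean signal of 3649.3 ± 245.4 against 182.3 ± 9.1 (SD, n = 2 each; log2 fold change 4.21, SE 0.15). MYL9, a regulatory light chain of myosin, stood at 1946.3 ± 25.6 against 195.6 ± 16.8 (3.21, SE 0.12). APLN, encoding the peptide ligand apelin (-2.39), CLDN5, encoding the tight junction protein claudin-5 (-2.50), CD34 (-1.52) and the guidance receptor gene ROBO4 (-1.30) fell. FABP4, a fatty acid binding protein, fell from 5085.3 ± 323.3 to 309.2 ± 10.1, a log2 fold change of -3.97 (SE 0.13). In total 828 genes rose and 746 fell of 13930 tested.

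The other large rises were in NRXN3, a neurexin of synaptic adhesion (log2 fold change 4.50, SE 0.46), GABBR2, a subunit of the GABA-B receptor (3.21, SE 0.16), RGS4, a regulator of G protein signalling (3.08, SE 0.15), and MEST, an imprinted gene (2.93, SE 0.11). HMGA2, an architectural protein of chromatin, rose by 2.90, the tight junction gene CLDN1 by 2.81, TMEM158 by 2.78 and ADAMTS1, a secreted metalloprotease, by 2.72. The largest fall was in DIPK2B, from 1311.8 ± 239.9 to 59.2 ± 13.4 (-4.14, SE 0.19). CHRNA1, a subunit of the muscle acetylcholine receptor, fell by 3.75. The glypican GPC5 (-3.64), SNCAIP (-3.35), the epoxide hydrolase EPHX4 (-3.26) and KIT, the receptor for stem cell factor (-3.25), fell too. So did the efflux transporter ABCG2 (-3.07), the homeobox gene MEOX2 (-2.98) and the sialyltransferase ST3GAL6 (-2.91). By the rule of choice all 20 passed in limma and had both ERG siRNA arrays outside the range of the 4 control arrays. Their limma adjusted p lay between 0.0034 and 0.0102. Means below the pseudocount of 16 were those of NRXN3 (15.7, arrays at 29.8 and 1.5) and TMEM158 (arrays at 9.5 and 12.5) with non-sense siRNA and of CHRNA1 (1.8 ± 0.1) and EPHX4 (14.7 ± 0.3) with ERG siRNA, so the sizes of these 4 changes depend on the pseudocount. For NRXN3 the log2 fold change was 6.15 with a pseudocount of 1, where it did not pass (adjusted p = 0.069), and 3.13 with 64, and it was 5.19 and 3.80 without non-sense siRNA replicates 1 and 2 (adjusted p = 0.060 and 0.063). With pseudocounts of 1 and 64 CHRNA1 stood at -6.35 and -2.13, and with 64 TMEM158 stood at 1.64 and EPHX4 at -2.12. Other probe sets did not all pass: those that did with the same sign were 0 of 5 for HMGA2 (4 had its sign), 1 of 2 for TAGLN, 0 of 1 for MYL9, 0 of 1 for FABP4 and 1 of 2 for ST3GAL6. With these 20 included, 651 higher and 696 lower genes met the rule. They passed the threshold here, had the same sign against vector and had both ERG siRNA arrays outside the control range.

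The endothelial identity and transcription factor lists were lower, while the junction list did not pass (adjusted p = 0.065). Of 38 measured endothelial identity genes 9 fell and 1 rose (10 and 3 adjusted over the list alone). The list as a whole was lower (mean log2 fold change -0.33, camera adjusted p = 0.0032; adjusted p = 0.349 with an estimated correlation). The 4 with the smallest p were APLN, ROBO4, CD34 and ANGPT2, which encodes the vessel-destabilising ligand angiopoietin-2 (-1.15), and the member that rose was THBD, encoding thrombomodulin (0.66). Of 29 endothelial transcription factors 4 fell, SOX18 (-1.63), BCL6B (-1.45), SOX7 (-0.85) and HEY2 (-1.12), and 2 rose, the flow-responsive factors KLF2 (1.93) and KLF4 (1.37). Adjusted over the list alone, 14 fell and 2 rose, and the list was lower (mean -0.28, adjusted p = 0.0028; adjusted p = 0.302 with an estimated correlation). KLF2 (limma adjusted p = 0.058) and KLF4 did not pass against vector, and KLF2 was lower with non-sense siRNA than with vector (-1.24). Against non-sense siRNA, 6 of 24 genes described elsewhere as activated by ERG fell and 1 rose (9 and 2 adjusted over the list alone). CLDN5 and SOX18 were among those that fell, and HMOX1, encoding haem oxygenase-1, rose by 2.00. That list was lower (mean -0.32, adjusted p = 0.0034; adjusted p = 0.349 with an estimated correlation). Part of its members may have been described from this series, so its direction is not independent evidence.

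The smooth muscle and fibroblast list was higher: 7 of 26 members rose and 0 fell (9 and 0 adjusted over the list alone), with a mean of 0.75 (adjusted p = 0.0013; adjusted p = 0.302 with an estimated correlation). Beside TAGLN and MYL9 its leading members were the collagen gene COL3A1 (2.44) and the tropomyosin gene TPM2 (2.00). Of 9 genes described elsewhere as repressed by ERG 2 rose and 0 fell (3 and 0 adjusted over the list alone), TAGLN and the neutrophil chemokine CXCL8 (1.73). The list was higher (mean 1.08, adjusted p = 0.017; adjusted p = 0.372 with an estimated correlation). CXCL8 may have been described from this series. The call was lost without ERG siRNA replicate 1 (mean 0.68, adjusted p = 0.146).

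The lists of oxidative stress and NRF2, hypoxia and glycolysis, unfolded protein and amino acid stress, and coagulation were higher with ERG siRNA. Of 23 NRF2 and oxidative stress genes 6 rose and 0 fell (7 and 1 adjusted over the list alone), led by HMOX1, the quinone reductase NQO1 (1.06), GCLM of glutathione synthesis (0.97) and GSR, glutathione reductase (1.32). The list mean was 0.40 (adjusted p = 0.0075; adjusted p = 0.350 with an estimated correlation). Of 30 hypoxia and glycolysis genes 3 rose, ANGPTL4 (1.34), the hexokinase HK2 (1.0) and LDHA (0.60), and ADM, which encodes the vasodilator peptide adrenomedullin, fell (-1.12). Adjusted over the list alone 4 rose and 1 fell, and the list mean was 0.30 (adjusted p = 0.0022; adjusted p = 0.350 with an estimated correlation). ASNS, asparagine synthetase (1.47), the transcription factor CEBPB (1.36) and PSAT1 of serine synthesis (0.85) rose among 29 genes of unfolded protein and amino acid stress, of which 0 fell (6 and 0 adjusted over the list alone). The list mean was 0.31 (adjusted p = 0.0028; adjusted p = 0.302 with an estimated correlation). Of 22 genes of coagulation and fibrinolysis 8 rose and 3 fell (10 and 3 adjusted over the list alone), led by the receptor kinase AXL (1.76), the urokinase gene PLAU (1.54), ENTPD1 (1.67) and the urokinase receptor PLAUR (1.26). Its members had a mean of 0.42 (adjusted p = 0.024; adjusted p = 0.371 with an estimated correlation). The coagulation call was lost without ERG siRNA replicate 1 (adjusted p = 0.079) or non-sense siRNA replicate 1 (adjusted p = 0.116), or with the upper 40% of probe sets tested (adjusted p = 0.051). The unfolded protein and coagulation lists did not pass against vector (adjusted p = 0.244 and 0.296), and the former was lower with non-sense siRNA than with vector (mean -0.17, adjusted p = 0.047; adjusted p = 0.287 with an estimated correlation). That last call was lost without non-sense siRNA replicates 1 and 2 (adjusted p = 0.078 and 0.058), control vector replicates 1 and 2 (0.116 and 0.087) or ERG siRNA replicate 1 (0.059). ENTPD1 (-0.16, adjusted p = 0.605) and ADM (-0.06, adjusted p = 0.843) did not pass against vector either, and non-sense siRNA differed from vector for both (-1.82 and 1.06).

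Interferon, mitotic and inflammatory lists were also higher than with non-sense siRNA. Of 40 interferon response genes 8 rose and 0 fell (12 and 1 adjusted over the list alone), led by the tether BST2 (1.61), IFI44L (1.37), the double-stranded RNA sensor TLR3 (1.51) and EPSTI1 (1.15). The mean of the interferon list was 0.45 (adjusted p = 5.54e-04; adjusted p = 0.372 with an estimated correlation). Of 37 mitosis genes 3 rose and 0 fell (3 and 0 adjusted over the list alone), ANLN (1.19), KIF23 (0.78) and ECT2 (0.79) of cell division. The mean of the mitosis list was 0.32 (adjusted p = 5.54e-04; adjusted p = 0.543 with an estimated correlation), and 0.21 without ERG siRNA replicate 1 (adjusted p = 0.032). Both lists stood lower with non-sense siRNA than with vector, as given in the comparison of the controls. Of 34 inflammatory and leukocyte adhesion genes 3 rose and 0 fell (3 and 0 adjusted over the list alone), the chemokines CXCL6 (2.16) and CXCL8 and the growth factor gene CSF1 (1.33). The mean of the inflammatory list was 0.61 (adjusted p = 0.016; adjusted p = 0.680 with an estimated correlation). That list rested on ERG siRNA replicate 1: without it the mean was 0.07 (adjusted p = 0.702), without replicate 2 it was 1.11, and without non-sense siRNA replicate 1 the adjusted p was 0.068. The adhesion receptor gene SELE read 3176.5 and 346.8 in the 2 ERG siRNA arrays against 914.9 and 1026.6 with non-sense siRNA.

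In the main fit none of the other lists reported here passed against non-sense siRNA. Camera adjusted p was 0.065 for endothelial junctions, 0.067 for DNA replication, 0.074 for basement membrane and matrix, 0.097 for the Notch pathway, 0.119 for cholesterol synthesis, 0.535 for TGF-beta and BMP signalling, and 0.646 for p53 targets, the Wnt pathway, heat shock, small RNA machinery and epithelial markers. It was 0.674 for leukocyte markers and 0.662 for erythroid markers, lists of which 8 and 3 members were measured. With no filter on dim probe sets endothelial junctions and Notch passed as lower and DNA replication as higher (camera adjusted p = 0.04995 each). DNA replication also passed with the mean of all probe sets per gene (0.045), and basement membrane and matrix passed as higher with a pseudocount of 64 (0.049). Across probe sets limma called 3162 of 32711 (1584 higher, 1578 lower), and 8976 had an unadjusted p under 0.05. Centring each array on its median moved the median log2 fold change of all probe sets from 0.02 to -0.09 and the split to 894 higher and 1574 lower, so the split of calls by direction depends on that choice, while the 12 lists kept their calls. The count fell to 560 without ERG siRNA replicate 1, 391 without replicate 2, 922 and 914 without control vector replicates 1 and 2, and 0 without either non-sense siRNA replicate, where 7049 (replicate 1) and 6951 (replicate 2) had an unadjusted p under 0.05.

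Against control vector, the other control of the design, ERG siRNA again gave higher TAGLN, MYL9 and CXCL8 and a lower endothelial identity list, together with a fall of the interferon response list (adjusted p = 0.296 for each of these lists with an estimated correlation, which ended both calls). TAGLN rose from 418.6 ± 66.4 to 3649.3 ± 245.4 (SD, n = 2 each; log2 fold change 3.08, SE 0.15), MYL9 by 2.47 and CXCL8 by 3.07. Of 40 interferon response genes 29 fell and 0 rose (36 and 0 adjusted over the list alone), led by IFI44L (-2.95), OAS2 (-3.05), IFI44 (-2.09) and the antiviral GTPase gene MX1 (-4.24). In total 240 genes rose and 436 fell of 13930 tested.

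Of 1574 genes past the threshold against non-sense siRNA, 471 passed against vector with the same sign, and 145 had the opposite sign there. The 20 named genes were chosen for the same sign against vector and for ERG siRNA arrays outside the control range. Their agreement was therefore partly built in: 18 of the 20 passed against vector as well. NRXN3 (3.03), CLDN1 (3.03), MEST (2.72), ADAMTS1 (2.19), RGS4 (1.99) and TMEM158 (1.96) rose, and DIPK2B (-3.70), FABP4 (-3.07), GPC5 (-2.90), KIT (-2.69), ABCG2 (-2.18) and ST3GAL6 (-2.14) fell. EPHX4 (-1.98), CHRNA1 (-1.92), SNCAIP (-1.78) and MEOX2 (-0.77) fell as well. With a pseudocount of 1 the calls of NRXN3 (3.30, adjusted p = 0.233), SNCAIP (adjusted p = 0.077), KIT (0.067) and MEOX2 (0.073) were lost. With pseudocounts of 1 and 64 CHRNA1 stood at -4.24 and -0.81, EPHX4 at -2.76 and -1.10 and TMEM158 at 2.38 and 1.28. GABBR2 (0.82, adjusted p = 0.057) and HMGA2 (0.52, adjusted p = 0.092) missed the threshold, and both were far lower with non-sense siRNA than with vector (-2.40 and -2.38).

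Among endothelial lists 4 were lower than with vector. Of 38 identity genes 7 fell and 0 rose (12 and 1 adjusted over the list alone), led by ROBO4 (-1.26), APLN (-2.08), the scaffold gene SHANK3 (-1.13) and the water channel gene AQP1 (-1.57). The list mean was -0.39 (adjusted p = 2.79e-04; adjusted p = 0.296 with an estimated correlation). Of 19 junction genes CLDN5 (-1.56) and JUP (-0.97), encoding plakoglobin, fell and 0 rose (8 and 3 adjusted over the list alone). The list mean was -0.24 (adjusted p = 0.034; adjusted p = 0.402 with an estimated correlation). SOX18 (-1.23) and BCL6B (-1.06) fell among 29 transcription factors and 0 rose (7 and 2 adjusted over the list alone). The mean of this list was -0.21 (adjusted p = 0.037; adjusted p = 0.296 with an estimated correlation). Of 24 genes described elsewhere as activated by ERG 4 fell, CLDN5, SOX18 and FZD4 (-1.10) among them, and HMOX1 rose (0.84). Adjusted over the list alone 7 fell and 1 rose, and the list mean was -0.25 (adjusted p = 0.030; adjusted p = 0.296 with an estimated correlation). Calls of the last 3 lists were lost without ERG siRNA replicate 1 (adjusted p = 0.080, 0.065 and 0.190, in this order) or control vector replicate 2 (0.099, 0.060 and 0.066), or with the upper 40% of probe sets tested (0.062, 0.113 and 0.059). The transcription factor call was also lost without ERG siRNA replicate 2 (adjusted p = 0.073).

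The inflammatory list was higher than with vector: 5 of 34 members rose and 0 fell (20 and 1 adjusted over the list alone), the chemokines CXCL6 (2.55), CXCL8 and CXCL5 (3.15), the prostaglandin synthase PTGS2 (2.28) and the superoxide dismutase SOD2 (1.79). Its mean was 1.54 (adjusted p = 1.99e-08; adjusted p = 0.396 with an estimated correlation). ERG siRNA replicate 1 stood above replicate 2 here too: the mean was 1.0 without replicate 1 (adjusted p = 4.88e-08) and 2.01 without replicate 2. With non-sense siRNA the inflammatory list was higher than with vector as well (mean 0.93, camera adjusted p = 5.30e-05, and 0.575 with an estimated correlation). With ERG siRNA against vector, genes described elsewhere as repressed by ERG had TAGLN and CXCL8 rising and 0 of 9 falling (6 and 0 adjusted over the list alone). Their mean was 1.85 (adjusted p = 4.32e-05; adjusted p = 0.296 with an estimated correlation). With non-sense siRNA against vector this list had a mean of 0.77, with 6 of 9 members higher, and did not pass in the main fit. ERG did not differ detectably between these controls, so the mean of 1.85 need not follow loss of ERG alone. Of 26 smooth muscle and fibroblast markers TAGLN, MYL9, COL3A1 (1.96) and TPM2 (1.09) rose and 0 fell (4 and 1 adjusted over the list alone). Their mean was 0.44 (adjusted p = 0.011; adjusted p = 0.296 with an estimated correlation). ANGPTL4 (0.76) and the glucose transporter SLC2A3 (0.82) rose among 30 hypoxia and glycolysis genes and 0 fell (5 and 0 adjusted over the list alone), with a mean of 0.23 (adjusted p = 0.0056; adjusted p = 0.296 with an estimated correlation). HMOX1 and the cystine transporter SLC7A11 (0.72) rose among 23 NRF2 genes and 0 fell (2 and 0 adjusted over the list alone), with a mean of 0.28 (adjusted p = 0.0031; adjusted p = 0.296 with an estimated correlation).

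Interferon and cell cycle lists were lower than with vector. The interferon list had a mean of -1.57 (adjusted p = 2.73e-22; adjusted p = 0.296 with an estimated correlation). Of 37 mitosis genes KIF20A (-0.87) and DLGAP5 (-0.76) fell and 0 rose (20 and 0 adjusted over the list alone). Their mean was -0.52 (adjusted p = 1.61e-10; adjusted p = 0.333 with an estimated correlation). Of 35 DNA replication genes CCNE2 (-0.76) and MCM7 (-0.65) fell and 0 rose (10 and 2 adjusted over the list alone). Their mean was -0.30 (adjusted p = 8.73e-05; adjusted p = 0.305 with an estimated correlation). In the main fit none of the other lists reported here passed. Their adjusted p was 0.051 for the Notch pathway, 0.070 for cholesterol synthesis, 0.201 for leukocyte markers, 0.244 for unfolded protein stress, 0.296 for coagulation, and 0.388 for heat shock and epithelial markers. It was 0.465 for p53 targets, 0.485 for basement membrane and matrix, 0.521 for TGF-beta and BMP signalling, 0.792 for the Wnt pathway, and 0.939 for small RNA machinery and erythroid markers. Some alternatives gained calls. The Notch list passed as lower with no filter (camera adjusted p = 0.020), a replicate block (0.035), centred arrays (0.044) or the 2 groups only (0.049). Cholesterol synthesis passed as higher with the upper 40% of probe sets (0.011), the mean of all probe sets per gene (0.020) or quantile normalization (0.026). Both passed with a pseudocount of 64 (0.0497 each).

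Limma called 1341 probe sets against vector (497 higher, 844 lower), with 7809 at an unadjusted p under 0.05. Centring each array on its median gave 276 higher and 802 lower, and a replicate block 27 higher and 23 lower. The count was 39 without ERG siRNA replicate 2 and 0 without any other single array, where between 5279 and 7892 probe sets had an unadjusted p under 0.05.

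A call against both controls required a change of the same sign relative to each of them, with the same ERG siRNA arrays in both. Of 13930 genes 182 rose and 289 fell against both, TAGLN, MYL9, MEST, CLDN1, CXCL6 and CXCL8 among the former and ERG, DIPK2B, FABP4, KIT, APLN and CLDN5 among the latter. Independent lists of the same lengths would share 14.3 higher and 23.3 lower genes, a number that leaves out the ERG siRNA arrays common to both comparisons. In 20 simulations with unchanged groups, in which these arrays were shared, the correlation of fold changes was 0.499 against the observed 0.666. The observed covariance of 0.148 lay above the simulated covariance of 0.026. The simulation gave all groups the same spread, however. Replicates of ERG siRNA, the shared group, lay further apart (SD of log2 difference 0.426, against 0.361 for non-sense siRNA and 0.343 for vector). The simulated covariance may therefore be too low. Part of the excess of shared calls may come from the shared arrays, which cannot be split with 2 per group. By probe set 353 rose and 570 fell against both (182 and 547 with arrays centred on the median), and this count of 923 was 28 without ERG siRNA replicate 2 and 0 without any other single array.

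**Figure D2:**
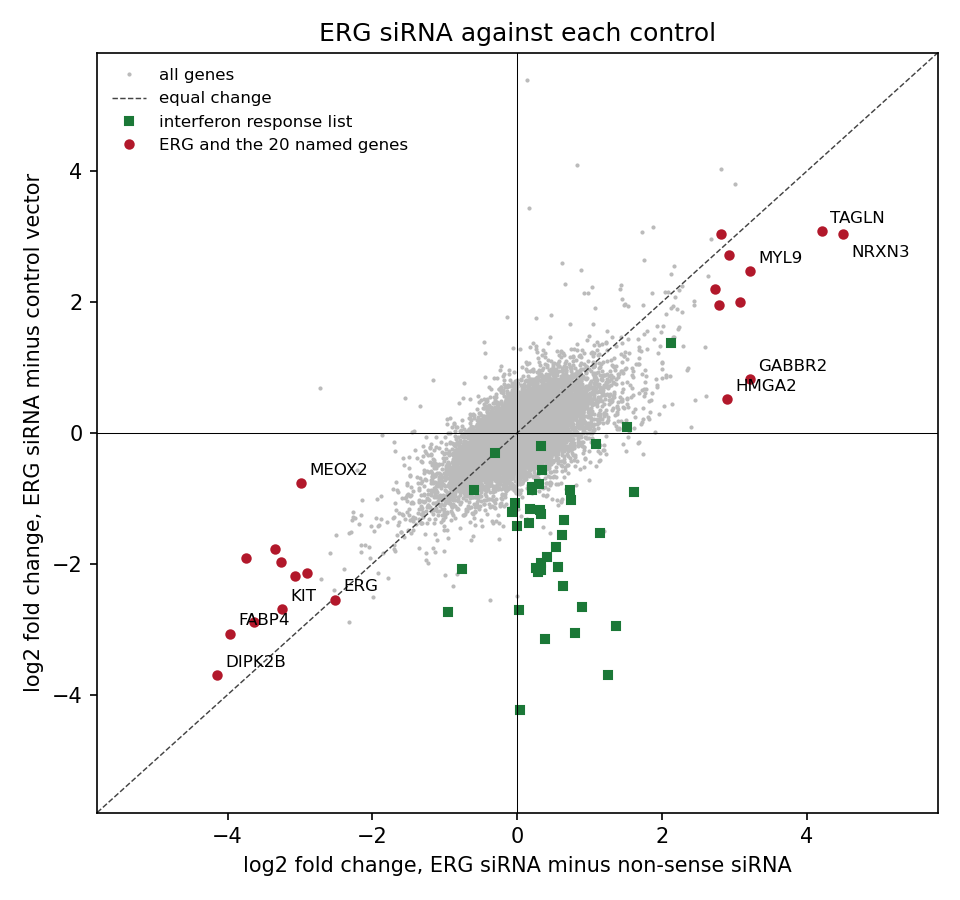
Log2 fold change of each of 13930 genes with ERG siRNA against non-sense siRNA (x axis) and against control vector (y axis), with the interferon response list as squares and ERG and the 20 named genes as large points. TAGLN (4.21 and 3.08) and DIPK2B (-4.14 and -3.70) lie far out in both, while GABBR2 (3.21 and 0.82) lies near 0 on the y axis and most interferon response genes lie below 0 on it.

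The comparison of non-sense siRNA with control vector gives the background between the controls, in which ERG did not differ detectably (log2 fold change -0.03, SE 0.14). Interferon response genes were far lower with non-sense siRNA. IFIT1, which binds foreign RNA, fell from 1458.3 ± 162.6 to 31.9 ± 10.3 (SD, n = 2 each; log2 fold change -4.96, SE 0.32), and so did IFI44L (-4.32, SE 0.13), MX1 (-4.27, SE 0.25), OAS2, a sensor of double-stranded RNA (-3.85, SE 0.15), and IFITM1 (-3.56, SE 0.21). Of 40 interferon response genes 28 fell and 0 rose (36 and 0 adjusted over the list alone). The list had a median of -1.78 and a mean of -2.01 (camera adjusted p = 3.31e-30; adjusted p = 0.287 with an estimated correlation).

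The largest rises were in KLRK1-AS1, an antisense RNA (3.42, SE 0.20), MEOX2 (2.21, SE 0.14), CD14, the co-receptor for bacterial lipopolysaccharide (2.08, SE 0.14), CD69 (1.97, SE 0.21) and the transporter gene ABCA4 (1.83, SE 0.13), with limma adjusted p between 0.016 and 0.034. The mean of ABCA4 with vector (4.2 ± 0.5) lay below the pseudocount, and its log2 fold change was 3.47 with a pseudocount of 1 (adjusted p = 0.073, not passed) and 0.81 with 64. In total 36 genes rose and 163 fell of 13930 tested.

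Cell cycle lists were lower with non-sense siRNA than with vector. Of 37 mitosis genes TOP2A (-1.32), KIF23 (-1.02) and NUSAP1 (-0.97) fell and 0 rose (37 and 0 adjusted over the list alone). Their mean was -0.84 (adjusted p = 1.85e-20; adjusted p = 0.287 with an estimated correlation). Of 35 DNA replication genes 0 passed in limma over all probe sets (15 lower and 0 higher adjusted over the list alone), and the list mean was -0.47 (adjusted p = 1.73e-09; adjusted p = 0.287 with an estimated correlation). The inflammatory list was higher (mean 0.93, adjusted p = 5.30e-05; adjusted p = 0.575 with an estimated correlation), with 0 of 34 members past the threshold over all probe sets and 7 higher and 0 lower adjusted over the list alone.

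Of 26 smooth muscle and fibroblast markers COL1A2 (-1.55) and TAGLN (-1.12) fell and 0 rose (9 and 1 adjusted over the list alone). Their mean was -0.31 (adjusted p = 0.019; adjusted p = 0.287 with an estimated correlation). TGFB1 (-1.30), TGFBI (-1.30) and TGFBR1 (-1.03) fell among 28 genes of TGF-beta and BMP signalling and 0 rose (8 and 2 adjusted over the list alone). Their mean was -0.22 (adjusted p = 0.047; adjusted p = 0.287 with an estimated correlation). The unfolded protein list (29 genes, mean -0.17, adjusted p = 0.047; adjusted p = 0.287 with an estimated correlation) and the heat shock list (18 genes, mean 0.15, adjusted p = 0.047; adjusted p = 0.287 with an estimated correlation) passed with 0 members past the threshold, over all probe sets or adjusted over the list alone. The calls of the last 4 lists were lost without either non-sense siRNA replicate, with adjusted p of 0.053 and 0.058 (smooth muscle), 0.069 and 0.082 (TGF-beta), 0.078 and 0.058 (unfolded protein) and 0.069 and 0.082 (heat shock) for replicates 1 and 2. All 4 were also lost with the mean of all probe sets per gene (0.061, 0.061, 0.061 and 0.063). Without control vector replicate 2 the TGF-beta, unfolded protein and heat shock calls were lost (adjusted p = 0.087 each). Without control vector replicate 1 the unfolded protein (0.116) and heat shock (0.073) calls were lost, as they were without ERG siRNA replicate 1 (0.059 and 0.062), and heat shock without ERG siRNA replicate 2 (0.066). Centring arrays on the median ended the TGF-beta (0.052), unfolded protein (0.066) and heat shock (0.061) calls, the upper 40% of probe sets ended the former 2 (0.066 each), and quantile normalization (0.355) or a fit to the 2 groups only (0.069) ended heat shock. A replicate block ended the TGF-beta (camera adjusted p = 0.058), unfolded protein (0.052) and heat shock (0.063) calls too.

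Of the remaining lists reported here none passed in the main fit. Their adjusted p was 0.106 for coagulation, 0.109 for p53 targets, 0.111 for leukocyte markers, 0.148 for endothelial transcription factors, 0.163 for genes described as activated by ERG and the Wnt pathway, 0.235 for basement membrane and matrix, and 0.24 for genes described as repressed by ERG. It was 0.480 for hypoxia and glycolysis, 0.538 for NRF2 genes, 0.676 for epithelial markers, 0.682 for erythroid markers, 0.709 for small RNA machinery, 0.940 for the Notch pathway, and 0.985 for endothelial identity, endothelial junctions and cholesterol synthesis. Quantile normalization gained calls of coagulation (camera adjusted p = 0.026) and basement membrane and matrix (0.008) as lower. Coagulation also passed with no filter (0.037). As higher, p53 targets passed with the mean of all probe sets per gene (0.040). Genes described as repressed by ERG passed as higher in a fit to the 2 groups only (0.029). Limma called 367 probe sets (74 higher, 293 lower), with 6156 at an unadjusted p under 0.05. The count was 1 without either ERG siRNA replicate and 0 without any other single array, where between 3922 and 4658 probe sets had an unadjusted p under 0.05.

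**Figure D3:**
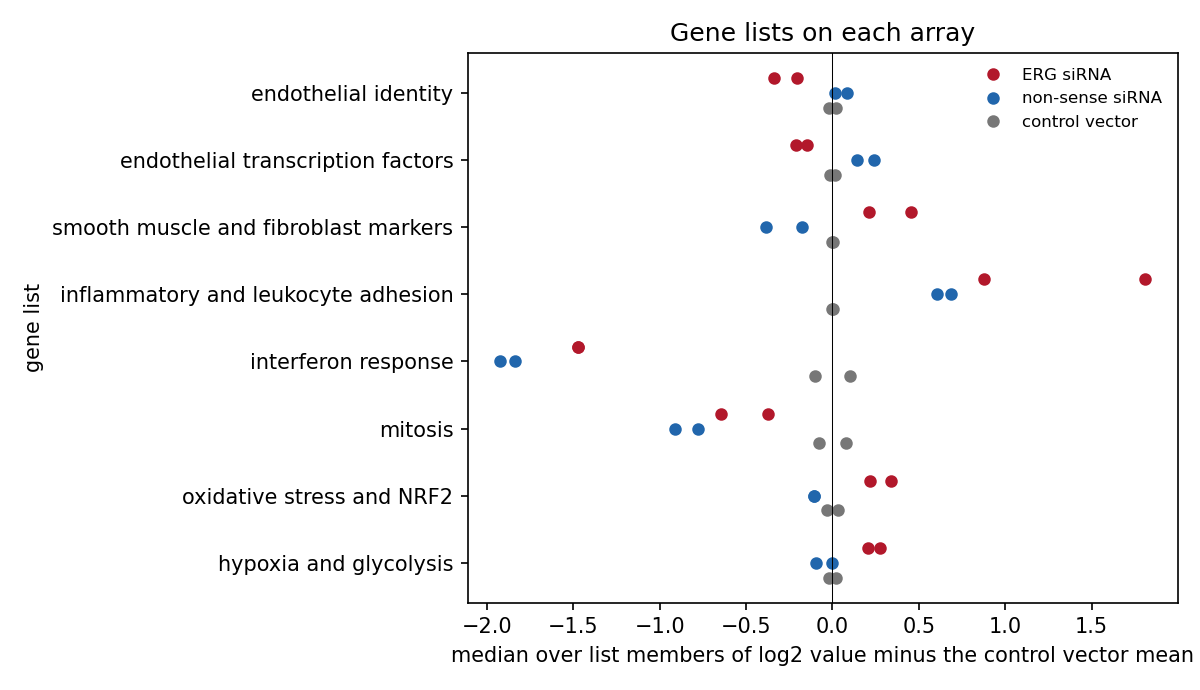
Median over the measured members of 8 gene lists (y axis) of the log2 value minus the mean of the control vector arrays (x axis), with a point per array. Interferon response lies between -1.92 and -1.47 in the 4 siRNA arrays, endothelial identity is lower in both ERG siRNA arrays (-0.34 and -0.20) than in the control arrays, and the inflammatory list differs between ERG siRNA replicates 1 (1.81) and 2 (0.88).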

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

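The tests of explanations below were all chosen after the results they bear on had been seen, while the comparisons and gene lists were fixed earlier. Groups of 2 arrays are too small for a test of single arrays that stand apart.

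The effect of ERG siRNA differed between the 2 controls for interferon response genes, with a list mean of 0.45 against non-sense siRNA and -1.57 against vector. This difference of -2.01 equals non-sense siRNA minus vector, since the ERG siRNA arrays cancel, so it is no separate test of ERG siRNA. Its camera result is that of the controls (adjusted p = 3.31e-30, and 0.287 with an estimated correlation). Mitosis genes differed in the same way, with list means of 0.32 and -0.52. The difference of -0.84 is again that of the controls (camera adjusted p = 1.85e-20, and 0.287 with an estimated correlation). By single genes, 7 passed against both controls with opposite signs, BST2, LY6E, IFI44L, OAS2, IFI35, PARP9 and EPSTI1, named after their values were seen. Each of these 7 was higher with ERG siRNA than with non-sense siRNA and lower than with vector, and 6 of them are in the interferon list. Their difference between the controls is the sum of these 2 changes, so it is no separate test.

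The pattern weighed here is the higher level of interferon response genes in the vector arrays than in both siRNA groups. Loss of ERG is argued against as its whole source, since the non-sense siRNA arrays, which belong to the pattern, had no such loss: their ERG log2 fold change against vector was -0.03 (95% interval -0.38 to 0.32). Array normalization is argued against as well, since the median after quantile normalization was -1.71 (95% bootstrap interval over genes -2.37 to -1.37). Infection with the vector may have raised these genes, and 35 of 40 members were higher in both vector arrays than in all 4 siRNA arrays. With no untreated group in the design this cannot be told apart from a fall caused by siRNA, and the design confounds the 2.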

How the results depend on the processing

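None of these alternatives was chosen after the results were seen. No called gene list, named gene or ERG level reversed its direction under any of them. The balance of counts by direction did turn with a replicate block. There 27 probe sets were higher and 23 lower with ERG siRNA than with vector (497 and 844 in the main fit). Against both controls 27 were higher and 15 lower (353 and 570 in the main fit). Counts of probe sets are given in the order ERG siRNA against non-sense siRNA, ERG siRNA against vector, non-sense siRNA against vector, and both controls. They were 1962, 353, 0 and 270 with a pseudocount of 1, where 5744 had an unadjusted p under 0.05 in the comparison with 0. With a pseudocount of 64 they were 5572, 3902, 2214 and 2355. With no filter on dim probe sets they were 1461, 243, 41 and 186, and with the upper 40% of probe sets 5571, 3886, 2157 and 2450. An intensity-dependent prior (limma-trend) gave 6719, 5081, 3703 and 3116, and an adjusted p under 0.1 gave 5708, 3492, 1423 and 2186. A minimum of 2-fold left 1259 and 703 with ERG siRNA against the 2 controls and 418 against both. Fits to only the arrays of the 2 groups compared gave 912, 0 and 1, with 7252 at an unadjusted p under 0.05 for the count of 0, and put the ERG log2 fold change against vector at -2.55 (adjusted p = 0.051). Quantile normalization gave 3312, 1473, 350 and 1029, and centring on the median left 243 for non-sense siRNA against vector. Replicate numbers do not pair the samples: deviations of same-numbered arrays from their group means correlated at 0.0075, -0.0179 and -0.0150, and a replicate block gave 1402, 50, 2 and 42 probe sets.

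With an estimated inter-gene correlation 0, 0 and 0 gene lists passed in the 3 comparisons. For non-sense siRNA against vector 5 lists passed with arrays centred on the median, 5 with the replicate block and 5 with the mean of all probe sets per gene, in place of 8. In the leave-one-out fits the lone array of a group is assumed to vary like the other groups, and calls were lost partly because fewer arrays leave fewer degrees of freedom. Without non-sense siRNA replicate 1 or 2 the count was 0 for ERG siRNA against non-sense siRNA, and it was 560 and 391 without ERG siRNA replicates 1 and 2 and 922 and 914 without control vector replicates 1 and 2. Against vector the count was 39 without ERG siRNA replicate 2 and 0 without each other array. For non-sense siRNA against vector it was 1 without ERG siRNA replicate 1 or 2 and 0 without each other array, and against both controls 28 without ERG siRNA replicate 2 and 0 otherwise. Lists passed for non-sense siRNA against vector numbered 4 and 5 without non-sense siRNA replicates 1 and 2 and 5 without control vector replicate 2. The ERG log2 fold change stayed between -2.65 and -2.39 against non-sense siRNA, where the call was lost at -2.39 and -2.65 without non-sense siRNA replicates 1 and 2. Against vector it was -2.48, -2.61, -2.55, -2.55, -2.57 and -2.52 without each array in turn, and the call was lost each time. Of calls in gene lists 28 were lost in leave-one-out fits, 32 with an estimated correlation and 18 under the other alternatives, and 13 and 19 were gained in the first and last of these. Of calls of named genes 200 were lost in leave-one-out fits and 64 under other alternatives. The cause of the other differences was not tested.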

Other observations

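The tests of explanations at the end of this part, and the counts of genes apart in the non-sense siRNA arrays, were chosen after the results were seen, while the gene lists were fixed earlier. The lists described in the next sentences did not pass as a whole against non-sense siRNA in the main fit. Of 28 genes of TGF-beta and BMP signalling 8 rose and 4 fell with ERG siRNA against non-sense siRNA (10 and 5 adjusted over the list alone). The signal transducer SMAD1 fell (-1.51) as did BMP4, encoding a ligand of BMP receptors (-1.29), while the matrix protein gene TGFBI (1.5) and the decoy receptor gene BAMBI (1.68) rose, and SMAD1, BMP4 and BAMBI also passed with the same sign against vector. Of 24 Notch pathway genes 5 fell and 1 rose (8 and 2 adjusted over the list alone), led by the feedback regulator NRARP (-1.15), the ephrin gene EFNB2 (-0.86), the target HES1 (-0.86) and the glycosyltransferase LFNG (-1.44). The mean of the Notch list was -0.25 (camera adjusted p = 0.097).

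Of 38 genes of basement membrane and matrix 8 rose and 1 fell against non-sense siRNA (14 and 3 adjusted over the list alone), led by ADAMTS1 (2.72), the matrix metalloprotease MMP10 (-2.27), the collagen COL8A1 (1.06) and the crosslinking enzyme LOX (0.85). Of 21 Wnt pathway genes 4 rose and 3 fell (5 and 4 adjusted over the list alone), led by APCDD1, an inhibitor of the pathway (2.08), CCND1, encoding cyclin D1 (1.05), DKK1 (0.82) and TCF7L1 (-1.12). Of 25 p53 targets and apoptosis genes 3 rose and 3 fell (3 and 5 adjusted over the list alone), with SESN1 (-1.31), BCL2L11 (-1.39) and DDB2 (-0.74) lower and GADD45B (0.84), FAS (0.61) and CASP8 (0.55) higher. Of 7 measured epithelial markers the keratins KRT19 (2.36) and KRT7 (1.75) rose and CLDN7 (-1.15) fell. LOX, BCL2L11 and KRT7 did not pass against vector (limma adjusted p = 0.427, 0.160 and 0.062). Non-sense siRNA differed from vector for each of them (-1.02, 1.01 and -1.08).

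Past the threshold in both comparisons, 111 genes were lower and 29 higher with non-sense siRNA than in either other group. Both comparisons contain the non-sense siRNA arrays, and the correlation of their fold changes (-0.5) lay beside that of simulations with unchanged groups (-0.499) while the covariance was larger (-0.0956 against -0.0258), so these counts are given as values alone. HMGA2 (2.90 for ERG siRNA minus non-sense siRNA, -2.38 for non-sense siRNA minus vector), GABBR2 (3.21 and -2.40), PLAAT3 (2.39 and -2.31) and RECK (2.45 and -1.95) were among those below both, and KLRK1-AS1 (-2.73 and 3.42) and MEOX2 (-2.98 and 2.21) among those above both. PLAAT3 had a log2 fold change of 0.08 between ERG siRNA and vector.

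A further pattern is the higher level of inflammatory genes in ERG siRNA replicate 1 than in replicate 2, by a median of 0.86 on the log2 scale, with 32 of 34 members higher in replicate 1. RNA degradation is argued against, since the 3' to 5' ratios of ACTB and GAPDH differed by at most 0.054 between the 2 arrays. Array scaling is argued against, since the median difference was 0.87 (0.49 to 1.35) after centring each array. The replicates of the other groups differed by a median size of 0.22 (non-sense siRNA) and 0.16 (control vector) over the same genes. No biological explanation was tested, since the design names no difference between the replicates.

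The last pattern weighed is the higher level of smooth muscle and fibroblast markers with ERG siRNA than with non-sense siRNA, which itself lay below vector (list mean -0.31, adjusted p = 0.019; adjusted p = 0.287 with an estimated correlation, 0.053 and 0.058 without non-sense siRNA replicates 1 and 2). A single cross-hybridising probe set is argued against only for genes with another probe set that passed with a rise. Of 12 other probe sets of the 7 genes that passed, 4 did so, against 4.84% of all probe sets (binomial p = 0.0020). That test takes the 12 as independent, though they share genes and arrays, so its p cannot decide for the list. The explanation stays open for 3 genes, MYL9 among them, of whose 4 other probe sets 0 rose over 2-fold. Smooth muscle or fibroblast cells in the cultures stay open. Of 10 of their matrix and surface genes, with no contractile gene included, 9 had a mean control signal of at most 50. The median log2 fold change of the 10 was 0.44 (-0.06 to 1.18), and 7 were higher, COL3A1 (2.44) and COL1A2 (1.80) most. The 7 include COL6A3 (0.14), which read 1.1 and 5.1 in the ERG siRNA arrays, and DCN (-0.06), THY1 (-0.13) and FAP (-0.22) were lower. TAGLN (4.21), MYL9 (3.21), TPM2 (2.00), CNN1 (0.90) and ACTA2 (0.66), which smooth muscle cells would bring, were higher as well, the last 2 without passing. The contractile genes named here were picked after their values were seen, and only 18 of the list's 26 measured members were higher. COL1A2 stood at 0.24 for ERG siRNA against vector (limma adjusted p = 0.531). Loss of ERG, named by the design, stays open beside such cells, as does an effect of this siRNA on other transcripts, since 1 siRNA group against ERG was analysed.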
